A study of Rattus norvegicus with 20 samples.

How the data were processed

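RNA was measured in skeletal muscle of Sprague Dawley rats by poly(A) RNA sequencing, with stranded libraries read from both ends on an Illumina NovaSeq per the labels. The 20 libraries fall into 4 groups of 5: gastrocnemius and soleus after a sham operation, and both muscles after hindlimb ischemia made by blocking the iliac and femoral arteries through a catheter. The time between the operation and the sampling is not given in the sources used here. Nor do the labels say whether the same number in different groups means the same rat. Within a treatment both muscles carry the same library number at the same replicate number, and sham and ischemia share no library number.

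The deposited table has 21926 gene entries with Ensembl rat identifiers and, for each library, an expected_counts column and an fpkm column. Per the file headers the first kind holds expected counts. The authors scaled the second kind, fpkm, by transcript length and by sequencing depth. The counts are whole numbers and were not scaled between libraries. Small counts pile up at multiples of 4: between 28.3% and 36.5% of the counts from 1 to 40 in each library are multiples of 4. The highest is sham soleus library 4, and the others have at most 32.4%. The number of counts per sequenced fragment is therefore uncertain, and the totals are not read here as numbers of fragments. The aligner, the counting program, the genome build and the annotation release are not given in the sources used here. Positions are those in the table.

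The total per library ranged from 53.6 to 85.4 M counts, with a mean of 67.3 M. The libraries have no molecular identifiers that the sources name, so precision is taken from the spread between the 5 libraries of a group and not from counting error.

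Genes with at least 1 FPKM in at least 5 of the 20 libraries were tested, which left 11693 genes. The counts were scaled with TMM factors and fitted with the edgeR quasi-likelihood model (edgeR 4.0.16, robust option, R 4.3.3) on all 20 libraries, with 1 term for each of the 4 groups. The tests are two-sided. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p below 0.05 were called. The standard error beside a log2 fold change is that change divided by the square root of its F statistic. Levels are CPM, counts scaled to library size with TMM factors, as mean ± SD of the 5 libraries of a group. The design named limma on log2(FPKM + 1) for a table without counts and the edgeR test for a table with counts, so the second was used.

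The comparisons were: ischemia against sham in gastrocnemius, ischemia against sham in soleus, the difference between these 2 responses (the interaction, gastrocnemius minus soleus), and gastrocnemius against soleus in sham and in ischemia. The choices made before the data were examined are the groups, the filter, the tests, the 31 gene lists with 530 genes, the rule for naming genes and most of the alternatives. The rule names, per comparison, the called genes with the largest rise and fall in log2(FPKM + 1), namely 6 each within a muscle and 5 each otherwise, with a gene symbol and a mean of at least 1 FPKM in the higher group. Where fewer than 4 genes were called in a direction it names the 4 with the smallest p. It adds 2 members of each of up to 6 called lists and a panel of reference genes (Myh7, Myh4, Vegfa, Hif1a, Ppargc1a, Trim63 and Fbxo32). Myh2 and Myh1, which the panel also named, were not analysed here.

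Gene lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, which compares a list with all other genes. Lists with at least 5 tested members were tested, 28 in all, with Benjamini-Hochberg adjustment over the lists. The lists for neutrophils, lymphocytes and inflammatory mediators had 1, 2 and 3 members past the filter and were not tested as lists. The others cover slow, fast and regenerating fibres, denervation and the neuromuscular junction, nuclear and mitochondrially encoded oxidative phosphorylation, the TCA cycle, fatty acid oxidation, glycolysis and glycogen, mitochondrial regulators, the hypoxia response, angiogenic factors, endothelial, mural, fibroblast, macrophage, adipocyte, Schwann cell, erythrocyte and tendon markers, extracellular matrix, the interferon response, atrophy and proteolysis, the Nrf2 and antioxidant genes, heat shock and the unfolded protein response, the cell cycle, the circadian clock and the immediate early genes. A second camera run estimated the correlation between genes from the data, and fry tested each list on its own. Beside the calls over all genes, list members were also adjusted over the list alone.

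Correlations of log2 fold changes are across genes, which are not independent replicates. Their null distribution comes from 100 random reassignments of treatment among the libraries of each muscle, made separately in each muscle or jointly for the same numbers in both. Single measures per library were compared with exact permutation tests, two-sided. The share of Myh7 is its percent of the sum of Myh7 and Myh4 FPKM. Myh2 and Myh1 are not in that sum, so it does not give the share of slow fibres.

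The model was tested on simulated data made from these libraries, with 100 genes changed by a log2 fold of 1 and 100 by 2. With edgeR the test recovered 36% and 90% of them for the gastrocnemius comparison, 46% and 84% for the soleus comparison, and 35% and 95% for the muscles in sham. It called 4, 7 and 5 genes that had not been changed. The changed genes were taken from those with higher counts, and the counts of each gene were drawn independently of other genes. Differences that many genes share between libraries, such as those of fibre mix or of sham soleus library 4, were thus not simulated. The percents and the false calls need not hold for the real libraries.

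The alternatives were other pseudocounts, no filter and a mean of at least 5 FPKM, median-of-ratios scaling, FPKM rescaled to an equal total, quantile normalization, each comparison with only its own groups, the fit without trend or robust option, library quality weights, a term for the replicate number, a slow minus fast fibre score as covariate, an added fold threshold, and each library left out in turn. Chosen after the data were seen were limma on log2(FPKM + 1), DESeq2 1.42.0, library totals alone, counts divided by 4, the settings that join another choice to leaving out sham soleus library 4, and a scan of the 307 KEGG pathways with 10 to 300 tested genes that the table itself names. No library was left out of the main results.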

Results

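The 20 libraries were 5 each of sham gastrocnemius, ischemic gastrocnemius, sham soleus and ischemic soleus of the rat. The gastrocnemius is mostly a fast muscle and the soleus a slow one. The mean total was 59.7 M counts per library in sham gastrocnemius, 67.7 M in ischemic gastrocnemius, 75.4 M in sham soleus and 66.3 M in ischemic soleus. Myh7 encodes the slow myosin heavy chain and Myh4 a fast one. Myh7 made up 98.9% ± 0.867 (SD, n = 5) of their sum in sham soleus and 98.0% ± 2.12 in ischemic soleus. In gastrocnemius it made up 12.0% ± 16.5 in sham and 24.0% ± 15.6 in ischemia, with single libraries from 0.536% to 40.5%. The Myh4 gene model overlaps that of Myh8 on the same strand, so its level is uncertain. Myh2 and Myh1 are not in the sum, so these percents are not shares of all myosin. Sham soleus library 4 stood apart: 8048 genes had at least 1 FPKM in it, against 10644 to 10876 in the other sham soleus libraries. Its median correlation with its group was 0.777, against 0.980 to 0.982 for the others, and its lead counts are given below with and without it. The plot of libraries shows these measures.

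**Figure D1:**
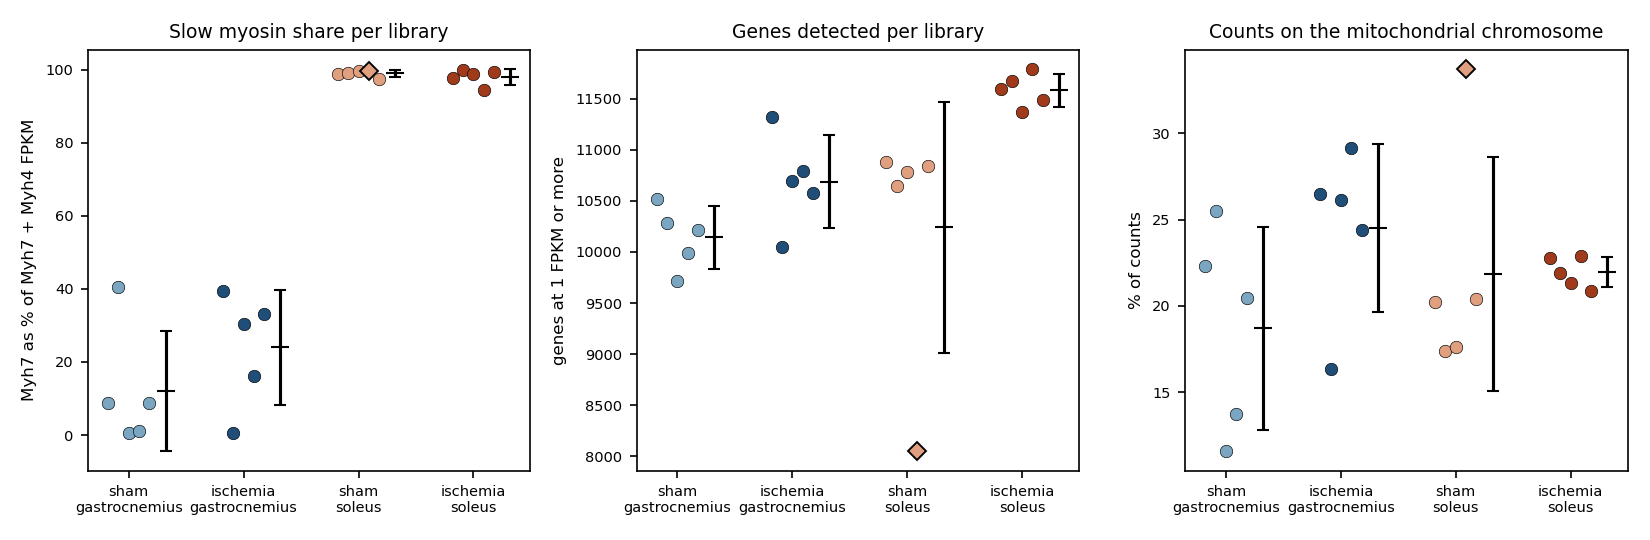
Myh7 as percent of the sum of Myh7 and Myh4 FPKM, genes at 1 FPKM or more and share of counts on the mitochondrial chromosome, by group, with a point for each of the 20 libraries, bars for mean and SD, and a diamond for sham soleus library 4. Sham soleus library 4 has 8048 genes at 1 FPKM or more, below the range of 10644 to 10876 of the other sham soleus libraries.

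In soleus, Nqo1 was lower after ischemia, and some genes of the extracellular matrix and its fibroblasts were higher. Of the named genes that passed, only Nqo1 passed under all alternatives. Nqo1, a quinone reductase of the antioxidant response (ENSRNOG00000012772, chromosome 19, 38422164 to 38437180), fell from 73.0 ± 18.6 CPM in sham to 25.6 ± 7.74 in ischemia (SD, n = 5 each), a log2 fold change of -1.51 ± 0.22 (SE, edgeR adjusted p = 0.0136). Adamts5, a protease that cleaves aggrecan, rose from 6.42 ± 2.98 to 22.9 ± 5.37 CPM, a log2 fold change of 1.83 ± 0.38 (adjusted p = 0.0388). Pdgfra, the receptor that marks fibro-adipogenic progenitors, rose from 20.7 ± 7.64 to 49.4 ± 10.8, a log2 fold change of 1.25 ± 0.27 (adjusted p = 0.0417). Col5a2, a chain of fibrillar collagen V, rose from 52.7 ± 18.4 to 165 ± 54.8, a log2 fold change of 1.64 ± 0.38. Smoc2, a calcium-binding matrix protein, rose with a log2 fold change of 1.27 ± 0.28 from 41.5 ± 6.36 CPM in sham. Scrn1 (secernin 1, 2.04 ± 0.46), Fgl2 (a fibrinogen-like protein of immune cells, 1.66 ± 0.39) and Gas7 (a cytoskeletal adaptor, 1.53 ± 0.36) rose as well. Among muscle and metabolic genes, the methyltransferase gene Mettl21c fell from 209.7 ± 64.9 to 70.8 ± 19.5 CPM, a log2 fold change of -1.57 ± 0.37. Adhfe1, a mitochondrial transhydrogenase, fell with -1.40 ± 0.28, and the histone H4 gene Hist2h4a with -1.44 ± 0.33. Echs1, an enzyme of fatty acid oxidation whose gene model overlaps Zfp710 on the same strand, fell with -0.85 ± 0.20 (adjusted p = 0.0493). Apobec2, a deaminase family member of muscle, and Ppp1r1a, an inhibitor of protein phosphatase 1, fell with -1.80 ± 0.40 and -1.70 ± 0.40. Without sham soleus library 4 these log2 fold changes were -0.98 and -0.95. In each of the 12 genes with the largest changes in log2(FPKM + 1), all 5 ischemic libraries lay on one side of all 5 sham libraries. These genes were chosen as called in the same libraries, so this adds no support. The plot of soleus genes shows their log2 fold changes.

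**Figure D2:**
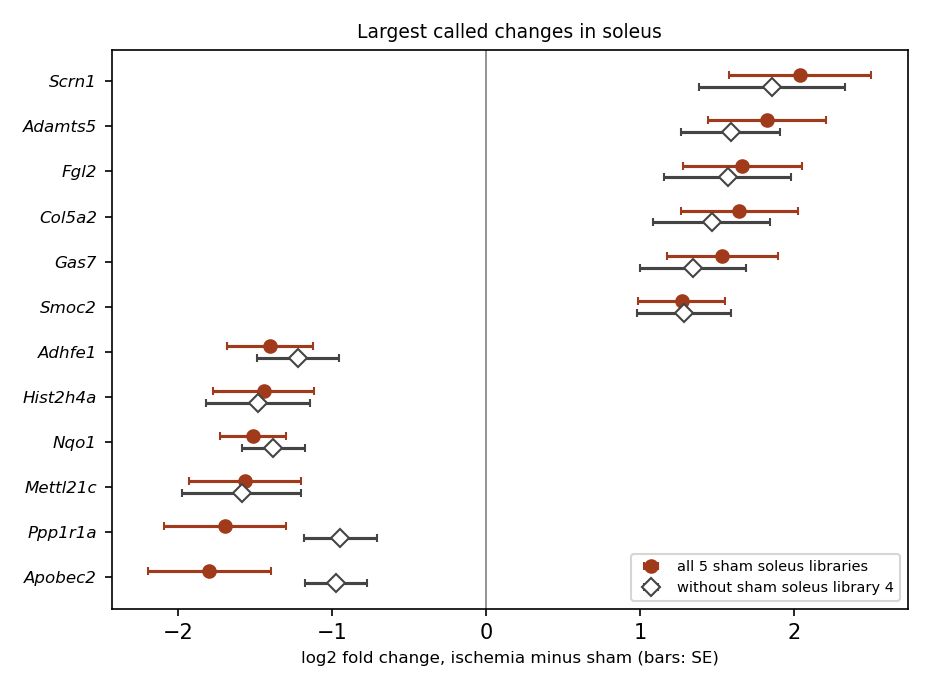
Log2 fold change (points) with SE (bars) of the 12 called genes with the largest changes in log2(FPKM + 1) in soleus, ischemia against sham, with all libraries and without sham soleus library 4. Nqo1 lies at -1.51 with all libraries and at -1.38 without that library.

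In all, 121 of 11693 genes passed the edgeR test in soleus, of which 62 rose and 59 fell, and 63 had a log2 change of at least 1. At an unadjusted p under 0.05 there were 3256. The ischemic and sham libraries did not overlap in 1580 genes, or 13.5%, where chance gives 0.794%. Without sham soleus library 4, 719 genes passed, 307 up and 412 down, including all 62 and all 59. DESeq2 called 1398 genes, 600 up and 798 down. Of the 14 named genes that passed, Nqo1 alone passed under all 40 alternatives, with log2 fold changes from -1.65 to -1.05. The count was 104, 106 and 87 without sham gastrocnemius 2, 3 and 4. It was 311 without sham gastrocnemius 1, 359 and 356 without ischemic gastrocnemius 1 and 2, and 737 and 548 without sham soleus 3 and 5. It was 2 without sham gastrocnemius 5, 1, 21 and 2 without ischemic gastrocnemius 3, 4 and 5, and 1 without sham soleus 1 or 2. It was 4, 3, 27, 1 and 23 without ischemic soleus 1, 2, 3, 4 and 5. Scaled by library totals alone, 387 genes were up and 11 down, with the median of all genes at 0.31 in place of -0.04 on the log2 scale.

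Among the gene lists in soleus, 3 rose and 4 fell by the camera test. The extracellular matrix list had 23 of 24 genes higher in ischemia, with a median log2 fold change of 1.47 (adjusted p = 2.22e-10, and adjusted p = 0.760 with an estimated correlation). Over all genes 1 of them passed, and 16 did when adjusted over the list alone. Its gene Fap, a protease of activated fibroblasts, had a log2 fold change of 1.73 ± 0.43 (adjusted p = 0.0521 over all genes). All 10 fibroblast markers were higher, with a median of 0.78 (adjusted p = 0.000215, and adjusted p = 0.760 with an estimated correlation), and 1 passed over all genes and 4 adjusted over the list alone. Of these the proteoglycan gene Dcn went from 295 ± 61.8 to 661 ± 72.8 CPM (edgeR adjusted p = 0.0637). Of 20 macrophage markers 15 were higher, with a median of 0.68 (adjusted p = 0.00085, and adjusted p = 0.760 with an estimated correlation), and 0 passed over all genes by edgeR. The scavenger receptor genes Cd163 and Mrc1 had log2 fold changes of 1.18 ± 0.41 and 1.31 ± 0.42. All 32 nuclear genes of oxidative phosphorylation were lower, with a median of -0.64 (adjusted p = 6.81e-08, and adjusted p = 0.760 with an estimated correlation), and 0 passed over all genes by edgeR and 23 adjusted over the list alone. Atp5f1b, the ATP synthase beta subunit, went from 3570 ± 1066 to 2348 ± 244 CPM, and Cox6a2, a muscle subunit of cytochrome oxidase, had a log2 fold change of -1.83 ± 0.56. Of 22 genes of fatty acid oxidation 21 were lower, with a median of -0.59 (adjusted p = 5.54e-06, and adjusted p = 0.760 with an estimated correlation), and 1 passed over all genes and 12 adjusted over the list alone. One of them, the acyl-CoA dehydrogenase gene Acads, had a log2 fold change of -1.59 ± 0.45. Of 14 genes of the TCA cycle 13 were lower, with a median of -0.31 (adjusted p = 0.00543, and adjusted p = 0.760 with an estimated correlation), and 0 passed over all genes by edgeR and 7 adjusted over the list alone. Its members Mdh2 and Idh3b, both mitochondrial dehydrogenases, had log2 fold changes of -0.67 ± 0.17 and -0.47 ± 0.16. All 13 mitochondrially encoded genes were lower, with a median of -0.83 (adjusted p = 0.0186, and adjusted p = 0.763 with an estimated correlation).

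Without sham soleus library 4 the matrix, fibroblast and macrophage lists had medians of 1.39, 1.23 and 1.09, and all 20 macrophage markers were higher. The nuclear oxidative phosphorylation list had a median of -0.25 in place of -0.64 (adjusted p = 4.34e-05, and adjusted p = 0.815 with an estimated correlation), with all 32 genes still lower. Adjusted over the list alone, 0 of its genes then passed in place of 23. Of fatty acid oxidation 1 gene passed in this way in place of 12, and of the TCA cycle 7 did as before. The mitochondrially encoded list then had a median of 0.03 (adjusted p = 0.935). The log2 fold change of Cox6a2 went from -1.83 to -0.27 and that of Acads from -1.59 to -0.58. The Schwann cell list, with a median of 1.11, and the mitochondrial regulators passed without it (adjusted p = 0.0185 each), and not with it (0.0620 and 0.224). With an estimated correlation none of the 8 lists passed without that library (adjusted p = 0.812 to 0.815). The other lists did not pass in soleus, with adjusted p from 0.0783 for the Nrf2 and antioxidant genes to 0.954 for the circadian clock. Between them lay angiogenic factors (0.116), slow fibre and endothelial genes (0.131 each), immediate early genes (0.245), atrophy (0.294), hypoxia, glycolysis, interferon and erythrocyte genes (0.375 each), regenerating fibre, denervation, adipocyte and heat shock genes (0.438 each), the cell cycle (0.506), mural and tendon markers (0.728 each) and fast fibre genes (0.913). In fast fibre, mural and circadian lists the median, the mean and the test differed in sign. Of the reference genes, Trim63, a ubiquitin ligase of muscle atrophy, had a log2 fold change of -0.64 ± 0.19 (adjusted p = 0.0638), and Myh7 one of -0.65 ± 0.80 (adjusted p = 0.637). For Myh4, Vegfa, Hif1a, Fbxo32 and Ppargc1a it was 0.25, 0.22, 0.06, -0.23 and 0.46, and none passed. Genes at 1 FPKM or more numbered 10239 ± 1228 in sham and 11582 ± 164 in ischemia (exact permutation p = 0.00794, two-sided, the smallest possible), and 10787 ± 102 in the 4 sham libraries other than library 4 (p = 0.00794).

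**Figure D3:**
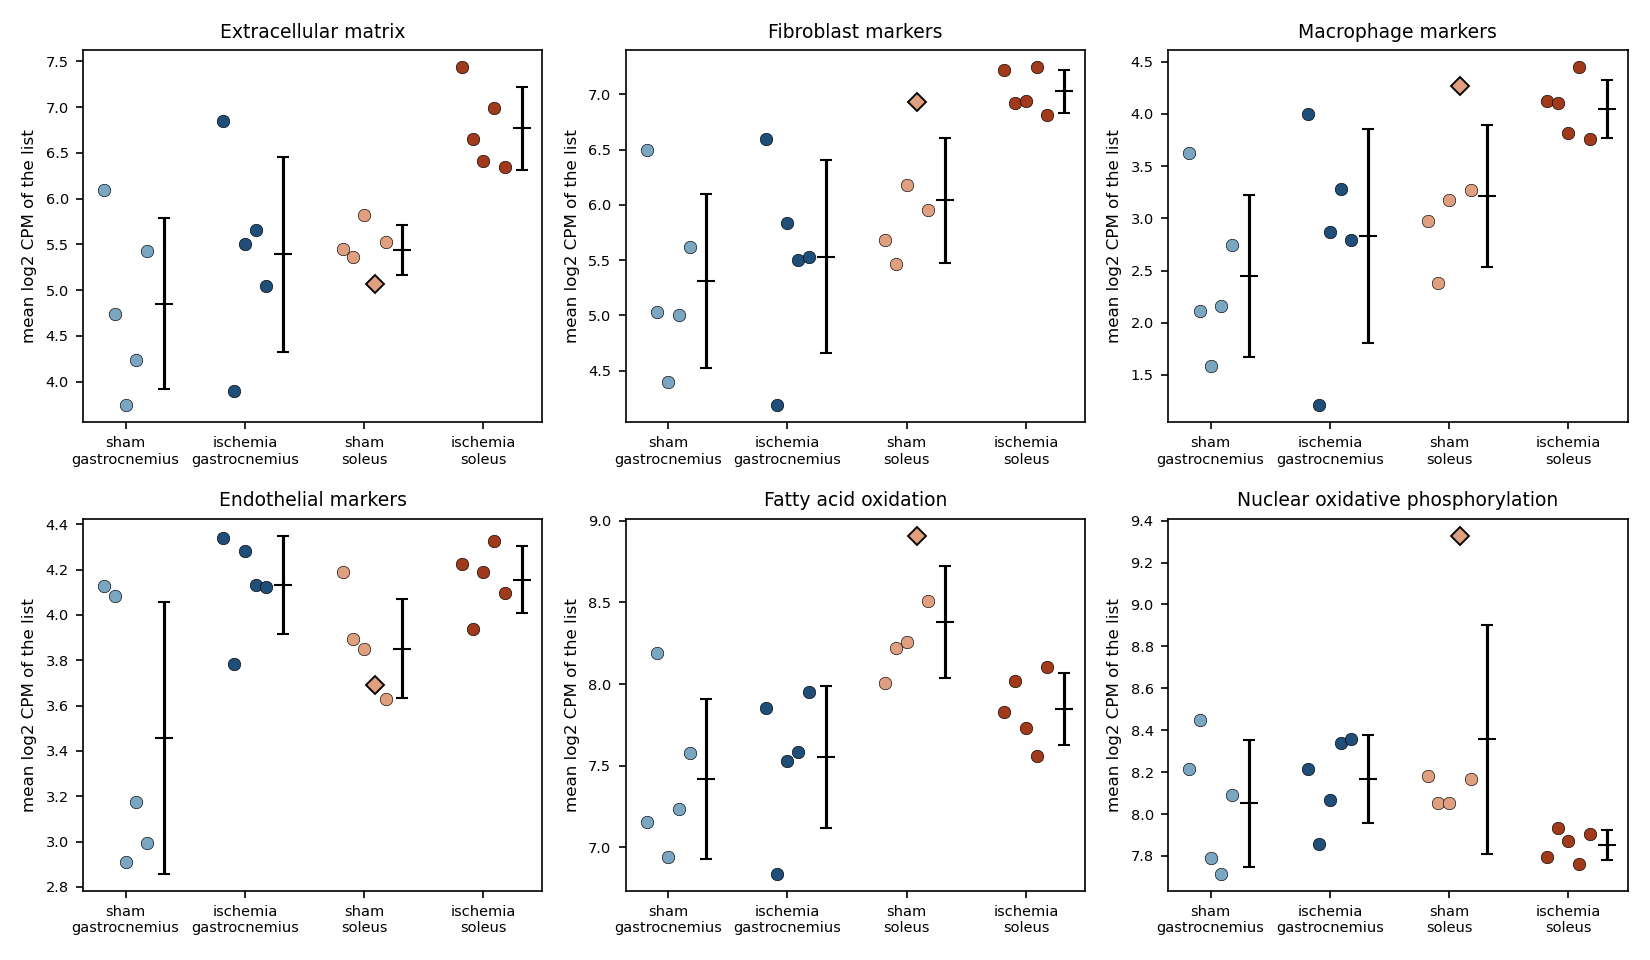
Mean log2 CPM of 6 gene lists by group, with a point for each library, bars for mean and SD, and a diamond for sham soleus library 4. In soleus the matrix list has a mean of 5.44 in sham and 6.77 in ischemia, and in gastrocnemius the endothelial list has 3.46 and 4.13.

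In gastrocnemius no single gene passed, and endothelial genes were higher in ischemia as a list (camera adjusted p = 2.25e-10), a call lost with an estimated correlation (adjusted p = 0.277). Cdh5, the cadherin of endothelial junctions, went from 54.5 ± 15.2 CPM in sham to 98.7 ± 20.3 in ischemia (SD, n = 5 each), a log2 fold change of 0.86 ± 0.20 (SE). Tie1, an endothelial receptor kinase, went from 24.0 ± 8.66 to 44.4 ± 12.8, a log2 fold change of 0.89 ± 0.27. All 17 endothelial genes were higher, with a median of 0.62. Over all genes 0 of them passed by edgeR, and 4 did when adjusted over the list alone. In the angiogenic list 13 of 15 genes were higher, with a median of 0.50 (camera adjusted p = 0.000155, and adjusted p = 0.323 with an estimated correlation), among them the endothelial nitric oxide synthase Nos3 with 0.66 ± 0.20 and thrombospondin 1 (Thbs1) with 1.76 ± 0.64. In the extracellular matrix list 22 of 24 were higher, with a median of 0.55 (0.000294, and adjusted p = 0.715 with an estimated correlation), including Loxl1, a collagen crosslinking enzyme, with 1.12 ± 0.58 and Col12a1, a collagen, with 0.97 ± 0.45. All 13 interferon response genes were higher, with a median of 0.36 (0.00163, and adjusted p = 0.590 with an estimated correlation), among them the transcription factor Irf1 with 0.37 ± 0.21 and the ISG15 protease Usp18 with 0.67 ± 0.34. All 11 slow fibre genes were higher, with a median of 0.78 (0.0023, and adjusted p = 0.715 with an estimated correlation), among them the Z-disc genes Csrp3 with 1.44 ± 0.82 and Myoz2 with 0.92 ± 0.76. The mural (median 0.14, 0.00957), macrophage (0.39, 0.0134) and mitochondrially encoded (0.29, 0.0415) lists also rose. With an estimated correlation these had adjusted p = 0.590, 0.833 and 0.835.

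Glycolysis and glycogen genes fell as a list in gastrocnemius, with 15 of 19 lower and a median of -0.37 (camera adjusted p = 0.000611, and adjusted p = 0.590 with an estimated correlation). Of these Ldha, lactate dehydrogenase A, went from 2618 ± 600.1 to 1945 ± 514 CPM, and hexokinase 1 (Hk1) went the other way with a log2 fold change of 0.77 ± 0.28. Atrophy genes fell with a median of -0.25, 16 of 20 lower (0.00338, and adjusted p = 0.323 with an estimated correlation). All 11 fast fibre genes were lower, with a median of -0.50 (0.00418, and adjusted p = 0.715 with an estimated correlation). With the slow minus fast fibre score as covariate 5 lists passed in place of 11. The endothelial (median 0.47 in place of 0.62, adjusted p = 6.94e-10), interferon (0.28 in place of 0.36, 0.0216) and atrophy lists (-0.17 in place of -0.25, 0.0216) were among them. Angiogenic (0.15 in place of 0.50, 0.0122) and glycolysis lists (-0.19 in place of -0.37, 0.0369) passed with medians that moved further. Of the lists that did not pass then, slow fibre had a median of -0.06 in place of 0.78, fast fibre -0.02 in place of -0.50 (0.578 each), macrophages -0.01 in place of 0.39 (0.754), the matrix 0.14 in place of 0.55 (0.243) and mitochondrially encoded genes 0.16 in place of 0.29 (0.408). The mural list did not pass either (0.0664), with a median of 0.13 in place of 0.14. Without sham gastrocnemius 3 or 4, 7 lists passed. The other lists did not pass, with adjusted p from 0.0595 for immediate early genes and 0.0750 for regenerating fibre to 0.946 for erythrocyte and heat shock genes. Between them lay the TCA cycle (0.179), nuclear oxidative phosphorylation (0.229), fatty acid oxidation and fibroblasts (0.271 each), tendon (0.272), hypoxia (0.331), the circadian clock (0.390), Schwann cells (0.449), denervation (0.565), mitochondrial regulators (0.618), Nrf2 and antioxidant genes (0.736), the cell cycle (0.814) and adipocytes (0.846). For hypoxia, adipocytes and heat shock the median, the mean and the test differed in sign.

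By edgeR 0 genes passed in gastrocnemius, with 727 at an unadjusted p under 0.05 and 585 expected by chance, and a smallest adjusted p of 0.692. DESeq2 called 11 genes, 9 up and 2 down, and 209 without sham soleus library 4. Library quality weights gave 571. The edgeR test called 6 without sham soleus library 4, all up, and 1 without sham gastrocnemius 2. Sham soleus library 4 is not in this comparison and bears on it only through the fit shared by all libraries. With only the groups compared 0 genes passed. The 6 genes, chosen after their values were seen, are Itpr2 (a calcium channel of the endoplasmic reticulum, 0.89 ± 0.13), Fryl (0.68 ± 0.10), Ccdc88c (1.15 ± 0.20), Prex2 (0.83 ± 0.14), Afdn (a junction protein, 0.94 ± 0.16) and Cd93 (an endothelial receptor, 1.20 ± 0.20). Sham and ischemic libraries did not overlap in 165 genes, or 1.41%, where chance gives 0.794%. Of the 27 genes that the rule named, which include those with the smallest p, none passed. Nid2, a basement membrane protein, went from 17.6 ± 0.831 to 32.6 ± 7.84 CPM (0.89 ± 0.20). The protocadherin Pcdh1 had a log2 fold change of 1.00 ± 0.21, the calcium channel Itpr3 0.85 ± 0.19 and Lzts1 1.48 ± 0.33. The ubiquitin ligase Trim13 (-0.68 ± 0.18), the histone gene Hist2h4a (-1.19 ± 0.33), the trafficking gene Trappc6b (-0.50 ± 0.15) and Kiaa0408L (-0.78 ± 0.22) were lower. Of the reference genes, Trim63 went from 262 ± 54.5 to 175 ± 15.1 CPM (-0.58 ± 0.19, edgeR adjusted p = 0.728) and the atrophy ligase Fbxo32 from 242 ± 218 to 112 ± 27.5 (-1.11 ± 0.49). For Myh7, Myh4, Vegfa, Hif1a and Ppargc1a it was 0.78 ± 0.80, -0.53 ± 0.61, 0.39 ± 0.37, 0.41 ± 0.31 and 0.66 ± 0.34.

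The smallest p for a difference between the ischemia responses of the muscles was that of Hs3st1, which encodes a heparan sulfate sulfotransferase. It went from 10.9 to 7.36 CPM in gastrocnemius and from 2.11 to 5.80 in soleus (n = 5 each). The interaction, gastrocnemius minus soleus on the log2 scale, was -2.03 ± 0.33 (edgeR adjusted p = 0.0652). Without sham soleus library 4 it was -2.17 ± 0.31 (adjusted p = 0.0148), the only gene that edgeR called then. Nqo1 had an interaction of 1.18 ± 0.30, and it went from 14.3 to 11.3 CPM in gastrocnemius. By edgeR 0 genes passed with all libraries, with 758 at an unadjusted p under 0.05, and DESeq2 called 2. Without sham gastrocnemius 2 there was 1. The apoptosis inhibitor Birc3 (-1.35 ± 0.30), the lysophospholipase Enpp2 (-0.90 ± 0.22), the cytoskeletal gene Specc1 (-0.82 ± 0.21), Fap (-1.74 ± 0.60) and the collagen gene Col3a1 (-1.69 ± 0.76) did not pass. Lzts1 (1.56), Lyrm7 (1.15), the taste receptor gene Tas1r2 (0.89), the slow troponin gene Tnni1 (2.31 ± 1.24), Csrp3 (2.16), Acads (1.63), Echs1 (0.89), Sdhb (1.11), Uqcrc1 (1.00), Mt-nd5 (1.12), Mt-nd6 (1.93), Mdh2 (0.76) and Idh3b (0.66) did not pass either, nor did the 7 reference genes. With sham soleus library 4 left out, the interaction was 1.32 for Tnni1, 1.60 for Csrp3, 0.63 for Acads and Sdhb, 0.57 for Uqcrc1, 0.42 for Mt-nd5, 0.25 for Mt-nd6, 0.78 for Lyrm7 and Echs1, 0.55 for Mdh2 and 0.52 for Idh3b.

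By camera with the preset correlation, the ischemia responses of oxidative genes differed between the muscles as lists, but these calls were lost with an estimated correlation. The number of lists called, 10, was as large in 39 of 100 regroupings of the libraries. All 32 nuclear oxidative phosphorylation genes had a positive interaction, with a median of 0.72 on the log2 scale (camera adjusted p = 2.69e-13, and adjusted p = 0.529 with an estimated correlation). Fatty acid oxidation had a median of 0.78 (4.09e-10), mitochondrially encoded genes 1.12 (6.87e-06), the TCA cycle 0.40 (7.55e-06) and slow fibre genes 1.73 (1.75e-05). These had adjusted p = 0.529, and the TCA cycle 0.451, with an estimated correlation. The Nrf2 and antioxidant list (0.38, 0.0133), endothelial genes (0.33, 0.0201) and regenerating fibre genes (0.69, 0.0275) were also positive, and had adjusted p = 0.529, 0.679 and 0.529 with an estimated correlation. Matrix genes had a median of -0.91 (7.55e-06) and fibroblast markers -0.68 (0.000759), and adjusted p = 0.591 and 0.542 with an estimated correlation. With sham soleus library 4 left out, the medians were 0.33 for nuclear oxidative phosphorylation, 0.26 for mitochondrially encoded genes, 0.57 for fatty acid oxidation, 0.44 for the TCA cycle, 1.20 for slow fibre genes, 0.31 for endothelial genes, -0.82 for the matrix and -1.01 for fibroblasts. These lists passed then, as did mitochondrial regulators (adjusted p = 0.00101), glycolysis (0.0249) and macrophages (0.000166), and regenerating fibre (0.228) and Nrf2 and antioxidant genes (0.356) did not. None of these 11 passed with an estimated correlation (adjusted p = 0.686). The other 18 lists had adjusted p from 0.0503 to 0.834, and for tendon, atrophy and circadian genes the median, the mean and the test differed in sign. Across genes, which are not independent replicates, the log2 fold changes of the 2 muscles correlated with r = 0.392 and rho = 0.440. In 100 random reassignments of treatment, made separately in each muscle, r was at most 0.365, and the permutation p = 0.0099 is the smallest these can give. When treatment was reassigned jointly to the libraries of both muscles with the same number, the median r was 0.124 and the permutation p = 0.0198 for r and 0.0396 for rho. With sham soleus library 4 left out, r was 0.409 (permutation p = 0.0693 separately and 0.129 jointly).

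In sham, gastrocnemius and soleus differed in the myofibril and in glycolysis. Myh4 was at 94859 ± 35926 CPM in gastrocnemius and 1556 ± 1182 in soleus (SD, n = 5 each), a log2 fold change of 5.93 ± 0.76. Actn3, the fast alpha-actinin, was at 13084 ± 6498 and 46.9 ± 17.5, a log2 fold change of 8.12 ± 1.16. Myh7 was at 3561 ± 4923 and 48570 ± 4924, a log2 fold change of -3.77 ± 0.89 (edgeR adjusted p = 0.00444). Ldha was at 2618 ± 600.1 and 293 ± 22.9 (3.16 ± 0.23, adjusted p = 1.03e-07), and pyruvate kinase Pkm at 4854 ± 1276 and 623 ± 62.8 (2.96 ± 0.25). Nqo1 was at 14.3 ± 2.53 in gastrocnemius and 73.0 ± 18.6 in soleus, a log2 fold change of -2.36 ± 0.22 (adjusted p = 1.17e-06). The myosin binding protein Mybpc2 (8.06 ± 0.97), parvalbumin Pvalb (7.82 ± 1.18) and tropomyosin Tpm1 (6.18 ± 0.69) were higher in gastrocnemius. Sarcolipin Sln (-5.46 ± 0.94), the stretch-response gene Ankrd2 (-4.95 ± 1.01), Tnni1 (-4.58 ± 1.00), the alpha myosin Myh6 (-4.36 ± 0.91), tropomyosin Tpm3 (-4.25 ± 0.83), troponin Tnnc1 (-4.09 ± 0.87) and the glutathione peroxidase Gpx1 (-3.14 ± 0.60) were higher in soleus. So were Cpt1b, the muscle carnitine transferase whose gene model overlaps Chkb on the same strand (-1.25 ± 0.19), and the flavoprotein gene Etfa (-1.01 ± 0.19). Trim63 was higher in gastrocnemius (0.68 ± 0.19, adjusted p = 0.0132). Fbxo32 passed as well (1.39 ± 0.49, adjusted p = 0.0462, and 0.279 without sham gastrocnemius 4). It lost its call in 27 of 38 alternatives, 15 of them with 1 library left out, and its log2 fold change ranged from 0.34 to 1.58. In all 2911 genes differed, 1330 higher in gastrocnemius and 1581 higher in soleus, and 4136 without sham soleus library 4. Scaled by library totals alone there were 808 and 1623, and by quantiles 1568 and 1269. Of the lists, glycolysis was higher in gastrocnemius, with 15 of 19 genes called and a median of 2.30 (camera adjusted p = 3.48e-26, and adjusted p = 0.0125 with an estimated correlation). The fast list was higher with all 11 genes called (median 5.35, 2.91e-19, and adjusted p = 0.0581 with an estimated correlation). The slow list was lower with all 11 called (-3.78, 7.28e-09), fatty acid oxidation with 17 of 22 (-1.0, 8.07e-07) and Nrf2 and antioxidant genes with 7 of 15 (-0.68, 0.00226). With an estimated correlation these had adjusted p = 0.357, 0.670 and 0.357. The median of the Nrf2 and antioxidant list was -0.34 with sham soleus library 4 left out (adjusted p = 0.0498, and adjusted p = 0.863 with an estimated correlation). The other 23 lists had adjusted p up to 0.748, and without sham gastrocnemius 1, 12 lists passed.

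In ischemia, fast fibre and glycolytic genes were higher in gastrocnemius. Myh4 had a log2 fold change of 5.15 ± 0.73 (SE, n = 5 each), Mybpc2 5.56 ± 0.87, Actn3 5.25 ± 1.02 and the fast troponin Tnnt3 5.05 ± 0.73. Parvalbumin Pvalb (4.73 ± 1.02), the Z-disc gene Myoz1 (4.15 ± 0.52), Pkm (2.61 ± 0.25) and Ldha (2.76 ± 0.23) were higher in gastrocnemius as well. Idh3a, a subunit of the TCA cycle enzyme isocitrate dehydrogenase, was at 401 ± 34.9 CPM in gastrocnemius and 156 ± 14.3 in soleus (1.36 ± 0.12, edgeR adjusted p = 1.09e-06), and the succinyl-CoA ligase Sucla2 had 0.98 ± 0.18. The anion exchanger Slc4a3 was at 19.8 ± 10.5 and 222 ± 75.9 (-3.49 ± 0.57). The matrix genes Dpt, at 71.8 ± 37.8 and 186 ± 30.1 (-1.38 ± 0.35), Fap (-1.36 ± 0.43) and fibrillin Fbn1 (-1.31 ± 0.36) were higher in soleus, as were the LIM protein Fhl2 (-2.80 ± 0.74) and gelsolin Gsn (-1.12 ± 0.30). Trim63 was higher in gastrocnemius (0.73 ± 0.19), and Myh7 did not pass (-2.34 ± 0.83, adjusted p = 0.0741). The slow fibre genes Sln (-2.98 ± 0.83), Tpm3 (-2.52 ± 0.77) and Tnnc1 (-2.62 ± 0.81) were higher in soleus. Leaving out each of the 20 libraries in turn ended the call of Fap 11 times, of Tpm3 and Tnnc1 9 times each, of Sln and Fbn1 4 times each and of Gsn 2 times. The highest edgeR adjusted p was that of Sln (0.0626), Tpm3 (0.0882) and Tnnc1 (0.0853) without ischemic gastrocnemius 4. For Fap (0.122) and Fbn1 (0.0708) it came without ischemic soleus 4, and for Gsn (0.0625) without ischemic gastrocnemius 2. In all 1473 genes differed, 920 higher in gastrocnemius and 553 higher in soleus. There were 3784 without sham soleus library 4, which is not in this comparison and bears on it only through the fit shared by all libraries. With only the groups compared there were 3685. Without ischemic gastrocnemius 2 there were 849. Scaled by library totals alone there were 441 and 2192, with the median of all genes at -0.38 in place of -0.03 on the log2 scale. Of the genes called, 715 were higher in gastrocnemius in both sham and ischemia (105 expected by chance), 403 were lower in both (74.8 expected) and 0 went opposite ways. Glycolysis (median 2.34, camera adjusted p = 1.23e-32), fast fibre (4.73, 8.16e-24), TCA cycle (0.52, 6.05e-06), nuclear oxidative phosphorylation (0.35, 0.00204) and mitochondrially encoded genes (0.61, 0.00661) were higher in gastrocnemius as lists. With an estimated correlation glycolysis and fast fibre passed (adjusted p = 0.00329 and 0.0153), and the others did not (0.163, 0.751 and 0.751). Matrix (-1.19, with 2 of 24 genes called, 5.79e-07), slow fibre (-2.26, 4.46e-06), fibroblast (-1.29, 7.24e-06), macrophage (-0.94, 6.60e-05), adipocyte (-2.15, 0.0063) and Schwann cell lists (-0.79, 0.00648) were higher in soleus, and had adjusted p = 0.558, and macrophages 0.610, with an estimated correlation. For regenerating fibre, endothelial and mural genes the median, the mean and the test differed in sign.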

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

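The covariate and leaving out each library in turn were planned. Their use as tests of an explanation, the other tests of sham soleus library 4, of the soleus lists and of the fibre mix, and the settings that join another choice to leaving out that library were chosen after the results were seen. The regroupings of the libraries were chosen earlier.

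Sham soleus library 4 lay far from the other sham soleus libraries in most measures taken per library. Its TMM factor was 0.495 (1.07 to 1.09 in the others), and 8048 genes had at least 1 FPKM in it (10644 to 10876). The 5 most abundant genes took 28.0% of its counts (20.3% to 20.6%), mitochondrial genes took 33.7% (17.4% to 20.4%), and its median correlation with its group was 0.777 (0.980 to 0.982). In gastrocnemius, sham library 2 had a Myh7 share of 40.5% (0.630% to 8.86% in the others), and ischemic library 2 had a slow minus fast score of -8.74 (-3.30 to -1.73). These are the 7 of 32 groups of library measures with one library far from the rest, where chance gives about 1 in 20. The share of multiples of 4 was not among these measures. It was 36.5% in sham soleus library 4 and 29.2% to 30.7% in the other sham soleus libraries.

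The same gap was looked for in the log2 CPM of the 83 named genes in 332 gene groups, and 47 showed it, where 16.6 are expected by chance. In sham soleus library 4 there were 30, of which Thbs1 (1.21), Fbxo32 (3.57), Hif1a (3.34), Nid2 (2.98), Adamts5 (0.81) and Sucla2 (7.19) were lower than in the other libraries. The other 24 were higher in it, namely Tie1 (5.50), Csrp3 (10.96), Myoz2 (12.27), Adhfe1 (4.87), Apobec2 (12.24), Ppp1r1a (8.25), Acads (10.08), Atp5f1b (12.42), Cox6a2 (11.77), Mdh2 (10.29), Idh3b (8.97), Mt-nd6 (14.35), Mt-nd5 (15.41), Sdhb (10.13), Uqcrc1 (10.56), Tnni1 (14.68), Lyrm7 (4.45), Sln (8.36), Ankrd2 (13.06), Tpm3 (13.93), Etfa (9.19), Gpx1 (11.37), Tnnc1 (12.73) and Slc4a3 (8.97). Ischemic gastrocnemius library 2 had 11, all lower than in the others, namely Myoz2 (3.16), Myh7 (7.58), Trim13 (0.73), Sdhb (7.53), Tnni1 (4.31), Ankrd2 (2.47), Myh6 (3.62), Tpm3 (5.40), Gpx1 (5.25), Tnnc1 (3.53) and Slc4a3 (1.58). Apart from these, Loxl1 (6.59) was high in ischemic soleus 1, Ppargc1a (4.52) in ischemic soleus 5 and Adamts5 (5.02) in ischemic soleus 4. Kiaa0408L (3.10) was low in ischemic soleus 4, Nos3 (3.56) in sham soleus 3 and Enpp2 (3.75) in sham gastrocnemius 2.

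For sham soleus library 4, the deviation from the group fell with gene length, with rho = -0.397 across genes (genes are not independent replicates) against -0.286 to 0.169 in the other libraries, and 83 of 86 ribosomal protein genes, which are short, were higher, with a median log2 difference of 2.15. This is consistent with a length bias such as degraded RNA or short fragments would give. A few abundant genes cannot be the whole cause, since the deviation had an SD of 1.81 on the log2 scale over all genes, against at most 0.822 elsewhere. A gastrocnemius sample under a wrong label is excluded by its Myh7 share of 99.65%. No biological explanation was tested, and none is given by the design for 1 library.

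The rise of matrix and stromal lists and the fall of oxidative lists in soleus was weighed next. Sham soleus library 4 is excluded as the whole cause for the matrix, fibroblast and macrophage lists, whose highest adjusted p without it was 6.22e-07, but it may account for the mitochondrially encoded list, with an adjusted p of 0.935 without it. A lower share of muscle fibres alone would raise the markers of every other cell type alike. Without that library the fibroblast score rose by 1.00 more than the mean of the endothelial and mural scores on the log2 scale (exact permutation p = 0.00794, two-sided). But fibroblasts (1.21) did not stand alone, since the macrophage (1.10), Schwann cell (1.27) and adipocyte scores (0.93) rose by similar amounts. The endothelial (0.26), mural (0.15), tendon (0.23) and erythrocyte scores (-0.02) moved less. The rise was thus not alike in all cell types, but a part of a lower fibre share in it is not excluded. A response of the soleus to ischemia, through more stromal cells or through their expression, stays open as a hypothesis, and no list passed with an estimated correlation (adjusted p = 0.760 to 0.763). In 100 regroupings of the libraries, chance can be excluded for the 121 genes (highest other 2, with 1 of the 100 as large) and for the 719 genes without that library (highest other 5, 1 of the 100), and not for the number of lists, 7 with it (highest other 10, 29 of the 100) and 8 without it (highest other 14, 53 of the 100).

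The endothelial, slow and fast fibre lists in gastrocnemius were weighed last. With the slow minus fast score as covariate the endothelial list had a median of 0.47 in place of 0.62, so most of its shift did not follow that score. It passed then by camera with the preset correlation (adjusted p = 6.94e-10). But that test called a median of 12 lists in the other regroupings of these libraries, so its p cannot exclude the mix of fibres in the piece sampled. Without the covariate the list had camera adjusted p = 0.277 with an estimated correlation, and the covariate was not run with one. For the slow and fast lists the mix of fibres cannot be told apart from ischemia, since the Myh7 share varied from 0.536% to 40.5% between libraries (exact permutation p = 0.317, two-sided, n = 5 each). Chance cannot be excluded for the number of lists, 11 (highest other 22, 69 of the 100 regroupings as large). For the 0 genes called by edgeR (727 at an unadjusted p under 0.05, 11 by DESeq2 and 571 with quality weights) the regroupings decide nothing, since all 100 must give as many. But one regrouping called 616 genes, which points to a structure of the gastrocnemius libraries other than sham and ischemia.

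The ischemia response differed between the muscles by a test of the interaction in 10 lists, with medians, gastrocnemius minus soleus on the log2 scale, of 0.72 for nuclear oxidative phosphorylation, 0.78 for fatty acid oxidation, 1.12 for mitochondrially encoded genes, 0.40 for the TCA cycle and 1.73 for slow fibre genes. With sham soleus library 4 left out, these were 0.33, 0.57, 0.26, 0.44 and 1.20. The medians were 0.38 for Nrf2 and antioxidant genes, 0.33 for endothelial genes, 0.69 for regenerating fibre genes, -0.91 for the matrix and -0.68 for fibroblasts, and 0.10, 0.31, 0.31, -0.82 and -1.01 with that library left out. None of the 10 passed with an estimated correlation (adjusted p = 0.451 to 0.679, and 0.686 to 0.689 with that library left out). Chance cannot be excluded for the number of lists, 10 (highest other 22, 39 of the 100 regroupings as large). For the 0 genes of the interaction called by edgeR (758 at an unadjusted p under 0.05, 2 by DESeq2, highest other 1) the regroupings again decide nothing, since all 100 must give as many. Chance can be excluded for the genes that differ between the muscles, 2911 in sham (highest other 1974, 1 of the 100) and 1473 in ischemia (highest other 295, 1 of the 100), and not for the number of lists in sham, 5 (highest other 20, 66 of the 100). That number does not speak to single lists, of which glycolysis passed with an estimated correlation (adjusted p = 0.0125).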

How the results depend on the processing

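DESeq2, limma on log2(FPKM + 1), library totals alone, counts divided by 4 and the settings that join another choice to leaving out sham soleus library 4 were chosen after the data were seen. Of 117 results on named genes 110 kept their direction under the alternatives run, and of the 54 that passed the test 31 passed under each. The 117 leave out reference genes that did not pass, namely 7 in the interaction and 3 and 5 between the muscles in sham and in ischemia. Of 112 list results 106 showed no counted turn of direction. Turns of lists called neither in the main test nor in the alternative were not counted. Of the 33 called, 30 kept their direction and 1 stayed called under each. The labels name no shared animal, but within a treatment they give both muscles the same library number at the same replicate number. The main fit has no term for such pairs. As a hint from the data, 4 of 5 same-number pairs of gastrocnemius and soleus correlated over 0.1 in ischemia (mean 0.252, against -0.0624 for other pairs) and 2 of 5 in sham (0.0608 against -0.00484), and 3 and 2 gastrocnemius libraries correlated best with their own number. Between treatments 1 of 5 did so over 0.1 in each muscle. With a replicate block for the number 0, 123, 0, 2161 and 1344 genes were called for gastrocnemius, soleus, the interaction, the muscles in sham and those in ischemia, and 77 of the 123 were among the 121 of the main test. The block joined the muscles within a treatment for the last 3 of these comparisons. For the first 2 it joined sham with ischemia, whose library numbers differ. Of the 125 called in soleus with only the groups compared, 37 were. Apart from the settings named here the cause was not tested. Whether depth limited the calls was not tested, since the totals are not read as numbers of fragments.

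Genes called in gastrocnemius were 571 with quality weights (340 up, 231 down), 11 with DESeq2, and without sham soleus library 4 also 7 with the number term, 2 with the covariate and 209 with DESeq2, and 0 to 6 leaving out one library.

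In soleus they were 852 (819 up, 33 down) and 525 (505 up, 20 down) with limma on log2(FPKM + 0.1) and log2(FPKM + 0.01), 1249 (1220 up, 29 down) on FPKM rescaled to an equal total, 1647 (1590 up, 57 down) on log2(FPKM + 1) and 398 with totals alone. The median of all genes then moved from -0.04 to 0.42, 0.44, 0.37, 0.31 and 0.31. They were 2 without a filter, 62 at a mean of 5 FPKM, 227 (98 up, 129 down) with median-of-ratios scaling, 401 (247 up, 154 down) with quantiles, 3057 with quality weights, 606 with the covariate, 63 at a fold threshold, 1398 (600 up, 798 down) with DESeq2 and 249 with counts divided by 4. Leaving out sham soleus library 4, they were 853 with the number term, 1759 with the covariate, 1659 with DESeq2 and 2680 with only the groups compared. Leaving out one library gave 1 to 737.

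The interaction had 1 gene with 0.1, 0.01 and 1 as pseudocount, FPKM rescaled to an equal total, quality weights, totals alone and the covariate without that library, and 2 with DESeq2, with the number term and with DESeq2 without that library, and 0 to 1 leaving out one library.

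Between the muscles in sham there were 1888 at a mean of 5 FPKM, 1387 with only the groups compared, 5267 with quality weights, 1632 at a fold threshold and 4433 with DESeq2 without that library, and 2065 to 4136 leaving out one.

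Between the muscles in ischemia there were 2850 (428 up, 2422 down), 2671 (415 up, 2256 down), 3371 (373 up, 2998 down) and 3516 (475 up, 3041 down) with the 4 limma settings in the order above, 2509 (1287 up, 1222 down) with quantiles, 2633 (441 up, 2192 down) with totals alone, 3685 with only the groups compared, 5105 with quality weights and 770 at a fold threshold. The median of all genes moved from -0.03 to -0.37, -0.38, -0.37 and -0.30 in these limma settings. Without that library there were 4696 with the number term, 4300 with DESeq2 and 3685 with only the groups compared. Leaving out one gave 849 to 3784.

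Lists called in gastrocnemius were 5 with the covariate and 6 with it without that library, in soleus 12 without a filter, and in the muscles in sham 8 with quality weights. With an estimated correlation they were 0, 0, 0 and 1 for gastrocnemius, soleus, the interaction and the muscles in sham, with fry 0 in the former 3, and the same without that library. Leaving out one gave 7 to 14, 7 to 10, 9 to 14 and 5 to 12. The correlation between muscles was 0.594 at a mean of 5 FPKM and 0.269 to 0.444 leaving out one.

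With the covariate the log2 fold change in gastrocnemius turned to -0.19 for Myoz2 (-0.17 without that library) and 0.023 for Myh4, that in soleus to 0.012 for Myh7 and -0.12 for Myh4 (-0.28 without that library), and the interaction of Tnni1 without that library to -0.017. The covariate is built from the slow and fast fibre lists, so turns of slow and fast fibre genes can follow from its construction. In soleus Fbxo32 turned to 0.52, 0.53, 0.48 and 0.42 in the 4 limma settings and 0.16 with quantiles. Hif1a turned to -0.13 with quality weights and, without that library, -0.16 with the number term, -0.13 with the covariate, -0.20 with DESeq2 and -0.15 with only the groups compared, and ranged from -0.18 to 0.23 leaving out one. Myh4 turned to -0.37 with quality weights and -0.36 with the number term without that library, and ranged from -0.43 to 0.79 leaving out one.

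On the scale of the signed -log10 of p, the slow fibre list in gastrocnemius turned to -0.381 with the covariate and -0.221 with it without that library. The covariate is itself built from this list. In soleus mitochondrially encoded genes turned to 0.640 with quantiles and 0.132 with the covariate without that library, the TCA cycle to 0.620 and glycolysis to 2.45 with quantiles. Mitochondrially encoded genes in the muscles in sham turned to 2.47 with quality weights, and adipocytes in gastrocnemius ranged from -1.84 to 1.28 leaving out one.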

Other observations

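The KEGG scan and its lists were chosen after the results were seen, and the test of the soleus against the gastrocnemius profile was chosen earlier.

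Genes of branched-chain amino acid breakdown were lower as a KEGG set in soleus without sham soleus library 4: of the 42 genes of the KEGG pathway Valine, leucine and isoleucine degradation 6 were higher in ischemia and the others lower, with a median log2 fold change of -0.44 (camera adjusted p = 4.58e-10, and adjusted p = 0.475 with an estimated correlation). Propanoate metabolism, which shares genes with it, had a median of -0.41 over 30 genes (2.70e-07, and adjusted p = 0.475 with an estimated correlation). The genes of Complement and coagulation cascades had a median of 0.98, with 37 of 42 higher (1.04e-07, and adjusted p = 0.475 with an estimated correlation). Genes of Lysosome (median 0.20 over 105 genes, 0.000478) and Phagosome (0.28 over 118 genes, 0.000331) were higher, while those of Proteasome (-0.16 over 45 genes, 0.000767) and Aminoacyl-tRNA biosynthesis (-0.19 over 46 genes, 5.56e-05) were lower. With an estimated correlation these had adjusted p = 0.475, and Proteasome 0.525. Of the 307 pathways 66 rose and 23 fell without that library, and 75 and 31 with it.

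In gastrocnemius the genes of ECM-receptor interaction were higher after ischemia in 51 of 54 cases, with a median of 0.53 (camera adjusted p = 1.02e-11, and adjusted p = 0.510 with an estimated correlation), and Cell adhesion molecules were higher with a median of 0.42 over 70 genes (8.42e-08, and adjusted p = 0.510 with an estimated correlation). Proteasome genes were lower, with a median of -0.24 over 45 genes (5.30e-09), as were Ribosome genes with -0.18 over 168 genes (0.000325), and these had adjusted p = 0.510 and 0.766 with an estimated correlation. In all 54 pathways rose and 12 fell, the same numbers without sham soleus library 4, and with an estimated correlation 0 passed in either muscle.

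One hypothesis was that ischemia moves soleus expression towards the gastrocnemius profile, which may be asked of all genes at once. Across genes, which are not independent replicates, the soleus difference between ischemia and sham, without sham soleus library 4, correlated with the difference of all gastrocnemius minus all soleus libraries with r = -0.157 and rho = -0.268. In 111 of all splits of these 9 soleus libraries, the real one included, r was as high (exact one-sided p = 0.881, highest other 0.286). The soleus side of the second difference holds the ischemic libraries too, so a real effect of ischemia enters it with the opposite sign and lowers r. The test did not bear the hypothesis out, but for this reason it cannot speak against it.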
